A study of Mus musculus with 12 samples.

How the data were processed

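RNA from laser-microdissected ventricular zone of the dorsal cortex was profiled in 12 mouse libraries, 3 in each of 4 groups. Per the labels' protocols, libraries were made with a directional RNA-seq kit from polyadenylated RNA. The submitters' processing notes name cutadapt 3.4, STAR 2.7.2b and RSEM 1.2.31 and the mouse build GRCm38 (mm10); the annotation release and the strand setting are not given in the sources used here. Per the file headers, the authors deposited for each gene an expected count, which RSEM estimates by sharing multi-mapped reads between genes and which need not be whole. The authors also deposited TPM and length for each gene, per the file headers. As RSEM defines them, TPM divides the count by effective length and scales each library to a fixed total, and the length is an average over a gene's transcripts weighted by abundance.

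Expected counts were rounded to whole numbers. Of 55487 gene identifiers, 55141 had a symbol and 55227 were found in the GENCODE annotation of GRCm38 used for names and coordinates. The 16798 genes kept by edgeR's filterByExpr were tested. Counts were scaled by TMM and fitted with edgeR 4.0.16 quasi-likelihood models (R 4.3.3) over all 12 libraries with 1 mean per group, which left 8 residual degrees of freedom, and the common biological coefficient of variation was 0.311. Comparisons were p18mKO2+ against p18mKO2- at each stage, their average, the difference of the p18 effect between stages, and E16.5 against E13.5 within each p18 status. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The printed SE is the absolute log2 fold change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes, and log2 CPM values a prior count of 2.

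Before the data were examined, 27 gene lists and the rule for named genes were fixed. The rule takes Cdkn2c, the 6 largest increases and 6 largest decreases among called genes whose groups do not overlap and whose mean TPM is at least 5 in the higher group (no overlap condition for the difference between stages, both stages for the average; unnamed, predicted, Riken and mitochondrial genes excluded), and up to 4 members of a list with the smallest p. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. Single values were tested by exact permutation. Folds against a group at 0 use a floor of 3 counts over the group; such bounds and counting intervals cover counting error only.

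The pipeline was tested on simulated counts for the 16798 genes with 200 genes changed. For the p18 effect at E13.5 it recovered 33.7% of 2-fold and 69.1% of 4-fold changes, for E16.5 44.0% and 73.0%, for the difference between stages 10.1% and 58.2%, and for the stage change in p18mKO2- 30.6% and 70.1%. The percentage of calls that were false was 4.9, 3.3, 8.2 and 7.5. These values come from 1 simulated set per comparison, with 73 to 121 calls each and genes drawn independently. They leave out shifts that many genes of a library share, so rates in the real libraries may differ.

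Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a mean CPM of at least 5, the replicate number as a block, the 6 libraries of the groups compared alone, and leaving out each library. Added after seeing the data were a Y-linked expression covariate, a covariate for the ribosomal RNA gene CT010467.1, leaving out the 2 libraries with transcripts of both sexes, a rescaling of Cdkn2c TPM by each library's median TPM over CPM, and 2 further gene lists. Figures were drawn with matplotlib 3.10.9. Some genes that the rule for named genes selects are not reported here.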

Results

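The data are RNA-seq profiles of the ventricular zone of the dorsal cortex of mouse embryos, cut out by laser microdissection. The ventricular zone lines the lateral ventricle and holds radial glia, the dividing progenitors of cortical neurons and astrocytes. The mice carried a conditional cassette in ROSA26 that, after Cre recombination, expresses the cyclin-dependent kinase inhibitor p18 (p18INK4c, product of Cdkn2c) together with the fluorescent protein mKO2, and tamoxifen was given to induce recombination. By the labels, p18mKO2+ libraries are from p18-overexpressing tissue and p18mKO2- libraries from normal tissue. There were 12 libraries in 4 groups of 3, p18mKO2- and p18mKO2+ at embryonic days E13.5 and E16.5. The total estimated count per library, in units of 1e6, lay between 17.1 and 21.84. The labels do not say whether the replicates are separate embryos or litters, so the p-values measure the spread between these libraries, which may be partly technical. The deposited names carry codes of a digit and a letter that may mark litter and embryo, in which case libraries of a group could share either and the p-values understate the spread between animals. The study's stated purpose was to examine how cyclin-dependent kinase inhibitors relate to the change from neuron to astrocyte production.

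The first comparison asked whether the targeted gene itself differed between the labelled groups. Cdkn2c (ENSMUSG00000028551, GRCm38 chromosome 4, 109660876 to 109667189, minus strand) was not called in the count test at either stage. At E13.5 it stood at 23.3 ± 5.08 CPM in p18mKO2- and 25.7 ± 5.997 CPM in p18mKO2+ (SD, n = 3 each), a log2 change of 0.14 ± 0.26 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.798). At E16.5 it stood at 23.1 ± 8.36 and 29.0 ± 2.76 CPM, a log2 change of 0.32 ± 0.26 (edgeR, adjusted p = 1). The deposited TPM of Cdkn2c was higher in p18mKO2+ at both stages without overlap of the groups, at 21.3 ± 5.25 against 30.2 ± 2.48 at E13.5 and 20.6 ± 7.56 against 38.0 ± 5.73 at E16.5. Over all exchanges of the p18 label within each stage, the TPM difference of 13.1 had an exact two-sided permutation p of 0.005 (Benjamini-Hochberg adjusted p = 0.015 over 3 measures, by exact permutation), and the CPM difference of 4.12 had an exact p of 0.235 (adjusted p = 0.235). Within 1 stage, 3 libraries against 3 cannot give an exact p below 0.1. The deposited length of Cdkn2c, averaged over its transcripts by abundance, was 258 bases shorter in p18mKO2+ (exact permutation p = 0.03, adjusted p = 0.045). Within 1 stage its groups overlapped (exact permutation p = 0.3 at E13.5 and 0.2 at E16.5). A shorter length raises TPM relative to counts, but TPM over CPM was also higher in p18mKO2+ across 11336 genes, by a median log2 of 0.17 at E13.5 and 0.27 at E16.5. With this library-wide part removed, a test chosen after seeing the data, the TPM difference fell from 13.1 to 9.07 (exact permutation p = 0.015). Within 1 stage the rescaled TPM had an exact permutation p of 0.3 at E13.5, where the groups then overlapped, and 0.1 at E16.5. The count test of Cdkn2c thus did not separate the groups and did not bear out the p18mKO2 labels, while the TPM difference ran in the direction they give.

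**Figure D1:**
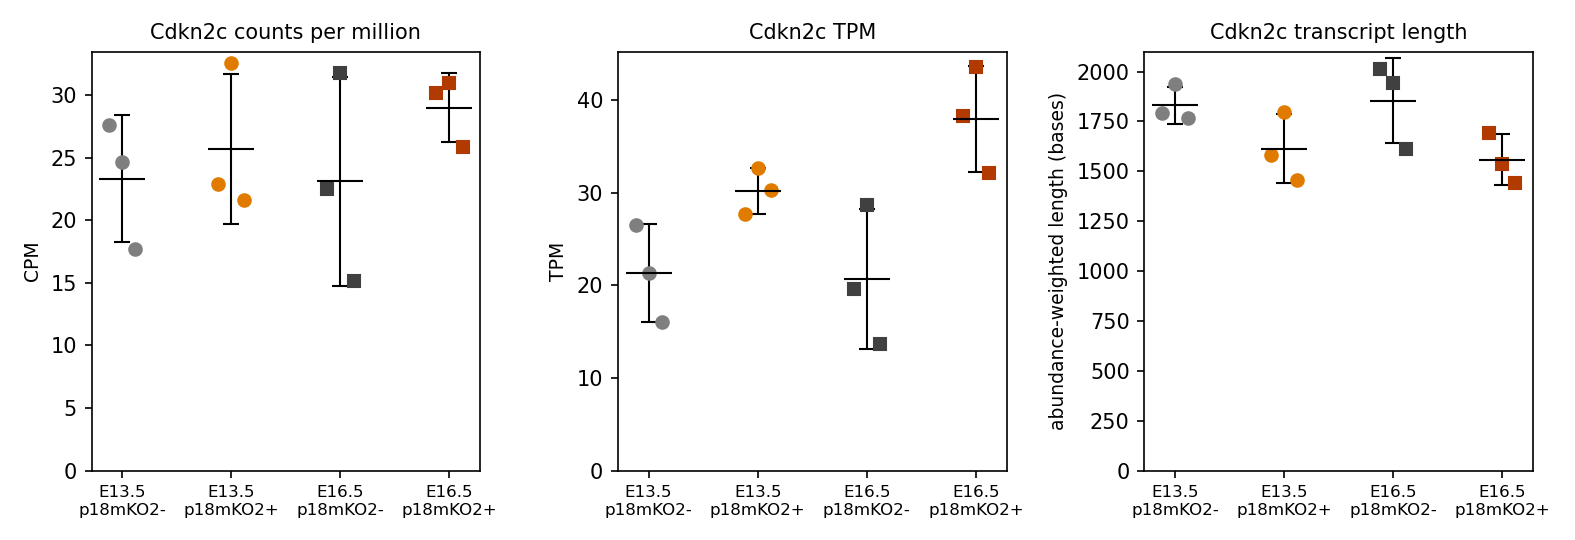
Cdkn2c in each library as CPM, as deposited TPM and as deposited abundance-weighted transcript length in bases. Points are libraries, long bars are group means and whiskers are SD (n = 3). TPM groups do not overlap within a stage, while CPM groups do.

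At E13.5, p18mKO2+ libraries held fewer transcripts of the cell cycle and more of differentiating neurons than p18mKO2- libraries. Of 30 genes of S phase and DNA replication, 24 fell and none rose (30 fell when adjusted over the list alone), with a median log2 change of -0.87. Slbp, which binds histone mRNA, changed by -0.87 ± 0.17 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00628), and Pcna, the sliding clamp of DNA polymerase, by -0.83 ± 0.17 (adjusted p = 0.0074). Of 28 genes of G2 and mitosis, 18 fell and none rose (28 fell adjusted over the list alone; median -0.77), among them Mki67 at -0.79 ± 0.15 and Ccnb2, a mitotic cyclin, at -0.96 ± 0.19. Of 18 pan-neuronal genes, 11 rose and none fell (15 rose adjusted over the list alone; median 1.08), including the microtubule-associated Dcx at 1.49 ± 0.15 and Mapt, which encodes tau, at 1.82 ± 0.28.

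Many neuron subtype genes also rose at E13.5. Of 12 deep-layer genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.87), with Bcl11b, a transcription factor of subcortical projection neurons, at 1.56 ± 0.19. Of 12 upper-layer genes, 7 rose and none fell (8 rose adjusted over the list alone; median 0.80), with the netrin receptor gene Unc5d at 1.77 ± 0.23 and the transcription factor gene Pou3f2 at 1.30 ± 0.19. Inhba, an activin subunit, had 3 counts over the E13.5 p18mKO2- group and 315 over the p18mKO2+ group, a ratio of 87.2 with a 95% counting interval of 29.6 to 425.

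With the preset inter-gene correlation of 0.01, camera called 13 of the 27 gene lists at E13.5, and with an estimated correlation it called 0. The S phase list had a camera adjusted p of 1.12e-21 with the preset value and 0.123 with the estimated one. The same pair of adjusted p-values was 2.62e-19 and 0.247 for G2 and mitosis, 5.07e-13 and 0.12 for pan-neuronal genes, 1.46e-06 and 0.12 for deep-layer genes, and 6.3e-09 and 0.0913 for upper-layer genes. The rotation test fry, which asks whether a list moves on balance in 1 direction, called these 5 among 7 lists.

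Glial and progenitor genes at E13.5 went in both directions. Of 20 radial glia genes, 2 rose and 7 fell (3 and 9 adjusted over the list alone; median -0.26; camera adjusted p = 0.0679), with Tnc, an extracellular matrix glycoprotein, at 2.03 ± 0.22 and the homeobox gene Emx2 at -1.02 ± 0.16. Of 16 genes of intermediate progenitors and neurogenic commitment, none rose and 3 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.0615). Of 23 astrocyte genes, 3 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.285). Aldh1l1, a folate enzyme used as an astrocyte marker, changed by 2.0 ± 0.23 and Luzp2 by 2.25 ± 0.36, while the gap junction gene Gja1 changed by -1.37 ± 0.26 and Fgfr3 by -1.75 ± 0.40. Of 24 gliogenic regulators, 2 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.452), with Etv5 at 1.55 ± 0.19 and Id4 at -1.23 ± 0.14. Among 11 oligodendrocyte lineage genes, 2 rose (camera adjusted p = 0.0453, and 0.379 with an estimated correlation), Olig1 at 1.88 ± 0.34 and Gpr17, with 3 counts over the p18mKO2- group and 101 over the p18mKO2+ group (ratio 28, 95% counting interval 9.3 to 138).

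Other lists called by camera at E13.5 with the preset correlation, but not with the estimated one, were G1 regulators (4 of 18 fell, 1 rose; adjusted p = 0.443 with an estimated correlation), Notch pathway (4 of 15 fell, Hes5 at -0.93 ± 0.22 and Hes1 at -1.07 ± 0.28; 0.542), hypoxia and glycolysis (7 of 17 fell, Ldha at -1.0 ± 0.20; 0.12), GABAergic and ventral telencephalon genes (3 of 14 rose, Gad1, which makes GABA, at 1.44 ± 0.38; 0.446), cytosolic ribosomal proteins (1 of 84 fell; 0.542), nuclear-encoded respiratory chain (0 of 75 called; 0.686) and erythroid genes (2 of 10 fell; 0.5). The erythroid genes that fell were the embryonic globins Hba-x at -1.98 ± 0.41 and Hbb-y at -1.92 ± 0.45. Endothelial and pericyte genes (2 of 15 rose; camera adjusted p = 0.0765) and p53 targets (2 of 14 rose; 0.799) were not called as lists. Camera also left uncalled, with no member called, CDK inhibitors (adjusted p = 0.799), Cajal-Retzius, hem and choroid plexus (0.67), microglia (0.799), meninges (0.129), immediate early and heat shock (0.35), interferon response (0.943), cholesterol synthesis (0.474) and mitochondrially encoded mRNAs (0.67).

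The largest increases by the rule for named genes were Rgs6, a regulator of G protein signalling (log2 change 4.46 ± 0.51; chromosome 12, 82588292 to 83162056), the melanocortin receptor gene Mc4r (4.33 ± 0.53), the neuropeptide gene Cck (4.15 ± 0.87), the dynein subunit gene Dync1i1 (3.85 ± 0.36), Hs3st4 (3.78 ± 0.38) and Nxph3 (3.36 ± 0.52). The largest decreases were P3h2, a collagen prolyl hydroxylase (-3.10 ± 0.50), Wfdc2 (-2.88 ± 0.54), Rps15a-ps6 (-2.78 ± 0.84), Fndc3c1 (-2.60 ± 0.33), Prr15 (-2.48 ± 0.40) and the axon guidance receptor gene Robo3 (-2.02 ± 0.46). Rps15a-ps6 is a pseudogene that may share reads with its parent gene, so its value is uncertain. Over all 16798 genes tested, edgeR called 1224 higher and 586 lower in p18mKO2+ (Benjamini-Hochberg adjusted p under 0.05), and 30.7% of genes had groups that did not overlap, against 10% by chance. The count of 1810 became 1140 without E13.5 p18mKO2- replicate 2, 927 without p18mKO2+ replicate 1 and 933 without p18mKO2+ replicate 3, and, in alternatives chosen after seeing the data, 796 without the 2 libraries that held transcripts of both sexes, 957 with Y-linked expression as a covariate and 729 with the ribosomal RNA level.

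**Figure D2:**
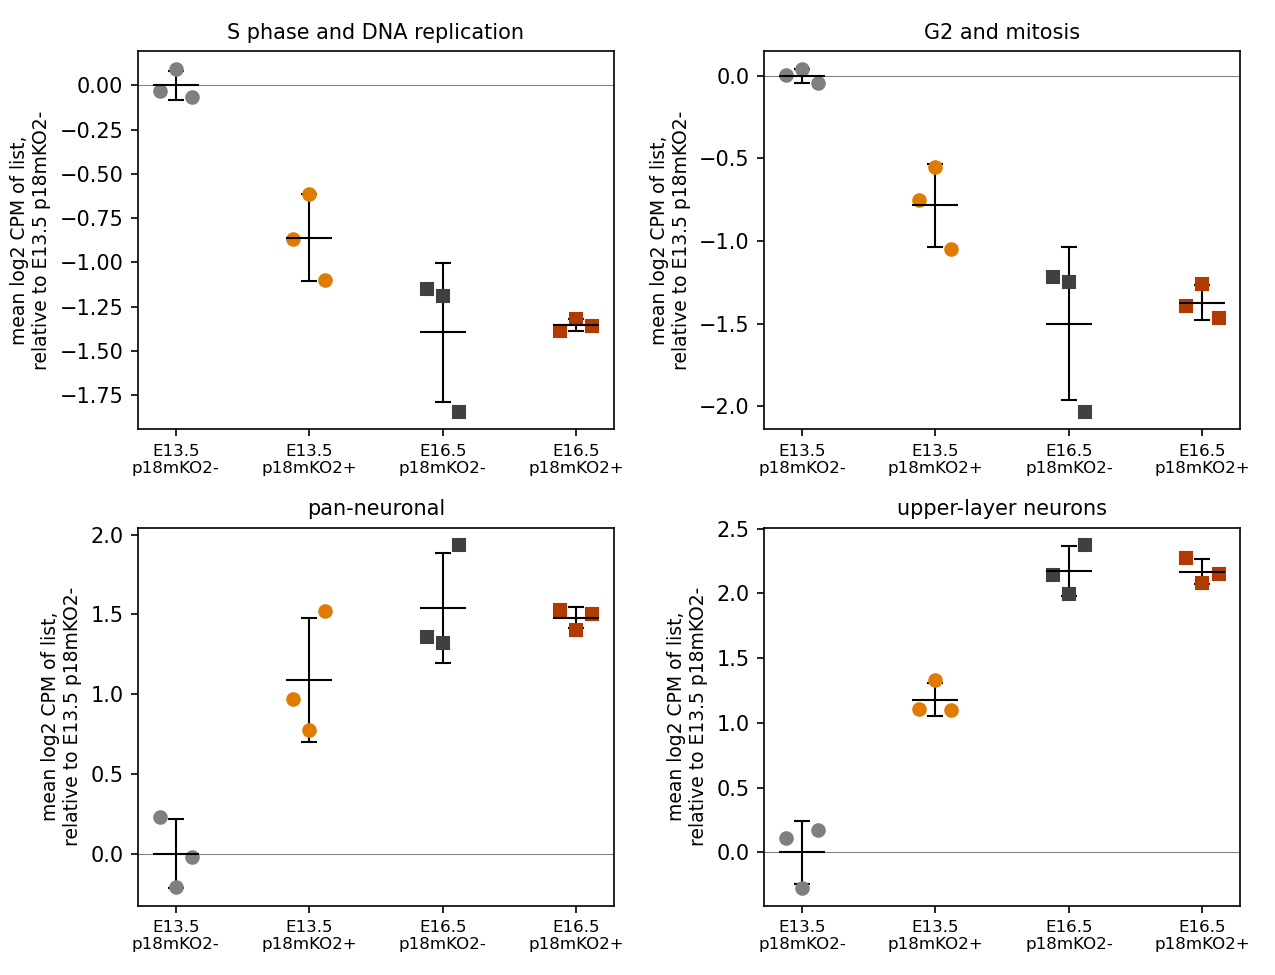
Mean log2 CPM of the members of 4 gene lists in each library, relative to the mean of E13.5 p18mKO2- (points: libraries; bars and whiskers: mean and SD, n = 3). At E13.5 each p18mKO2+ library lies below each p18mKO2- library for both cell cycle lists and above it for both neuronal lists.

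At E16.5, edgeR called 0 genes between p18mKO2+ and p18mKO2-. At an unadjusted p under 0.05 there were 426 genes, fewer than the 840 that chance alone would give over independent genes, and the smallest adjusted p was 0.154. DESeq2 called 16, limma-voom 2 and edgeR without a filter on low counts 81. Without E16.5 p18mKO2- replicate 3 or E16.5 p18mKO2+ replicate 3 the count was 1. Genes whose groups did not overlap made up 7.9%, against 10% by chance. Of 14 GABAergic and ventral telencephalon genes, 0 were called over all genes and 8 were higher when adjusted over the list alone, with a median log2 change of 1.19. Dlx2, a homeobox gene of the ganglionic eminences, stood at 1.42 ± 0.32 (SE; edgeR adjusted p = 0.899), Gsx2 at 1.40 ± 0.42 and Dlx5 at 1.17 ± 0.30 (adjusted p = 1 for both). Camera called this list with the preset correlation (adjusted p = 2.61e-18) and did not with an estimated one (adjusted p = 0.108). The 23 astrocyte genes had a median of 0.16, with Aldh1l1 at 0.81 ± 0.22 and Clu at 0.80 ± 0.32, neither called (camera adjusted p = 0.000867, and 0.292 with an estimated correlation). Camera with the preset correlation also called, each with an adjusted p of 0.96 with an estimated correlation and with no member called, G2 and mitosis (adjusted p = 0.0452), Notch pathway (0.0205), Cajal-Retzius, hem and choroid plexus (0.0205; median 1.28), ribosomal proteins (4.9e-11; median -0.20) and respiratory chain (0.0133). The Cajal-Retzius, hem and choroid plexus list rose in p18mKO2+ replicate 2 alone (0.61, mean log2 CPM relative to E13.5 p18mKO2-). Replicates 1 and 3 (-1.018 and -1.607) lay within the range of E16.5 p18mKO2- (-1.875 to -0.915). The S phase (0.914), pan-neuronal (0.26) and upper-layer (0.936) lists were not called by camera at E16.5. Simulated 2-fold changes in this comparison were recovered in 44.0% of genes and 4-fold changes in 73.0%, so smaller or more variable changes could go undetected at this depth and replication.

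**Figure D3:**
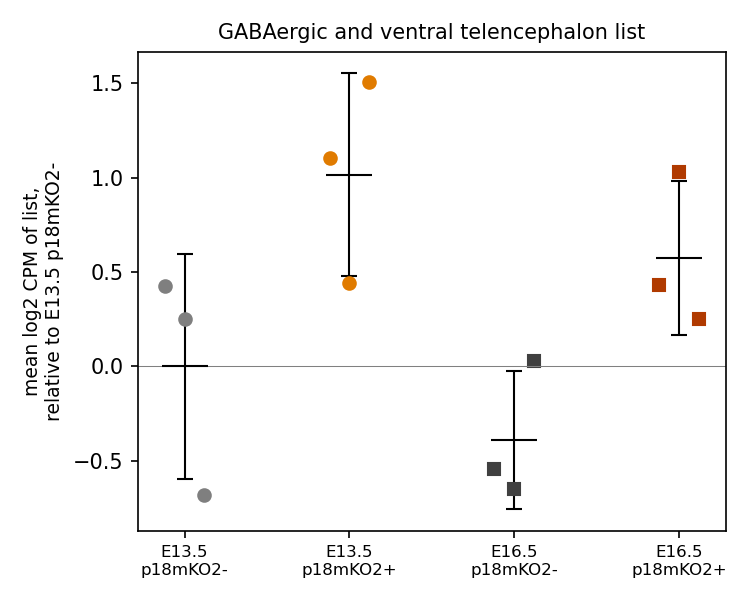
Mean log2 CPM of the 14 GABAergic and ventral telencephalon genes in each library, relative to the mean of E13.5 p18mKO2- (points: libraries; bars and whiskers: mean and SD, n = 3). At E16.5 all p18mKO2+ libraries lie above all p18mKO2- libraries, while at E13.5 the lowest p18mKO2+ library (0.442) and the highest p18mKO2- library (0.427) nearly meet.

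Averaged over both stages, p18mKO2+ libraries held more transcripts of several ventral telencephalon and astrocyte genes. Six3, a homeobox gene of the ventral forebrain, changed by 1.74 ± 0.38 (SE, log2; edgeR adjusted p = 0.0342), and its antisense neighbour Six3os1 by 2.03 ± 0.31. Because the strand setting of the counting is not given in the sources used here, reads of this pair may not be separated. Aldh1l1 changed by 1.41 ± 0.16, Gad2 by 1.28 ± 0.29, the GABA transporter gene Slc6a11 by 1.23 ± 0.15 and Pak6 by 1.14 ± 0.25. The largest decreases were Smco4 (-0.86 ± 0.19), Cenps (-0.73 ± 0.17), Pi4k2b (-0.65 ± 0.15), Dnaaf2 (-0.65 ± 0.15), the histone mRNA binding gene Slbp (-0.61 ± 0.12) and the nucleolar gene Nop56 (-0.60 ± 0.13). Of 14 GABAergic and ventral genes 5 rose (11 adjusted over the list alone), and of 23 astrocyte genes 3 rose and 1 fell (4 and 2 adjusted over the list alone); with an estimated correlation camera called neither (adjusted p = 0.143 and 0.279). Of 30 S phase genes 3 fell (25 adjusted over the list alone; camera adjusted p = 2.62e-17, and 0.153 with an estimated correlation). The median of this list was -0.87 at E13.5 and -0.01 at E16.5, so its averaged fall came from E13.5. edgeR called 308 genes higher and 66 lower. The total of 374 was 245, 244, 141 and 185 without E13.5 p18mKO2- replicates 2 and 3 and p18mKO2+ replicates 1 and 3, and 85, 750, 70, 173 and 182 without E16.5 p18mKO2- replicates 2 and 3 and p18mKO2+ replicates 1, 2 and 3. It was 1127 with DESeq2 and 1271 without a filter, and, in alternatives chosen after seeing the data, 90 without the libraries of both sexes, 17 with Y-linked expression as a covariate and 0 with the ribosomal RNA level.

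The difference of the p18 effect between stages tested whether p18mKO2+ and p18mKO2- differed by unlike amounts at E13.5 and E16.5. edgeR called 453 genes. Of 12 splits of the libraries within stages that kept the real E13.5 groups, 7, the real one included, gave at least as many calls. The real E16.5 groups thus did not stand out. Of the 453 genes, 50 had a more positive effect at E16.5 and 403 a more negative one. Neuronal genes were among the latter, with Dcx at -1.53 ± 0.22 (SE, log2, E16.5 effect minus E13.5 effect; edgeR adjusted p = 0.00241), Hs3st4 at -4.10 ± 0.49 and Unc5d at -1.79 ± 0.31. Of 18 pan-neuronal genes 4 were called and of 12 upper-layer genes 5 (15 and 6 adjusted over the list alone), all more negative. Of 28 G2 and mitosis genes 2 were called (26 adjusted over the list alone), Kif23 at 0.90 ± 0.22 and Ccnb2 at 1.07 ± 0.26. With an estimated correlation camera called none of the 27 lists. The total was 246 and 200 without E13.5 p18mKO2- replicate 2 and p18mKO2+ replicate 1, 225, 124 and 179 without E16.5 p18mKO2+ replicates 1, 2 and 3, 1122 with DESeq2 and 1168 without a filter, and, chosen after seeing the data, 149 without the libraries of both sexes and 295 with the Y-linked covariate.

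Between E13.5 and E16.5, p18mKO2- libraries lost cell cycle transcripts and gained neuronal ones. All 30 S phase genes and all 28 G2 and mitosis genes fell (the same numbers adjusted over the list alone; medians -1.33 and -1.42), and 16 of 18 pan-neuronal and 9 of 12 upper-layer genes rose (16 and 10 adjusted over the list alone). Of 23 astrocyte genes 6 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.209). Pou3f2 changed by 2.83 ± 0.20 (SE, log2; edgeR adjusted p = 5.91e-07), Aldh1l1 by 2.34 ± 0.23, Tnc by 4.01 ± 0.23 and the Notch target Hes5 by -2.48 ± 0.23. The embryonic globins Hbb-y and Hba-x changed by -8.69 ± 0.64 and -6.48 ± 0.53. Wnt8b, a Wnt ligand gene of the cortical hem, was at 0 counts in all E16.5 p18mKO2- libraries and at least 217-fold lower than at E13.5, against a floor of 3 counts over the group. Inhba had 3 counts at E13.5 and 1359 at E16.5 (ratio 466, interval 159 to 2260). By the same floor Scrg1 was at least 57.3-fold and Defb11 at least 18.9-fold higher, and Hsd3b6 at least 83.5-fold and Wnt3a at least 28.5-fold lower. Eif2s3y, at least 357-fold higher, lies on the Y chromosome and follows the sex of the embryos. Of the E16.5 p18mKO2- libraries only replicate 2 held more than traces of Y-linked transcripts (168 CPM, against 0.06 and 0.23 in replicates 1 and 3). edgeR called 2760 genes higher and 2245 lower. Only the upper-layer list kept its camera call with an estimated correlation in this comparison (adjusted p = 0.0219).

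In p18mKO2+ libraries edgeR called 182 genes higher and 93 lower at E16.5 than at E13.5. Of 12 upper-layer genes 7 rose (8 adjusted over the list alone; median 1.07), with Pou3f2 at 1.38 ± 0.19 (SE, log2; edgeR adjusted p = 0.00207), and the list kept its camera call with an estimated correlation (adjusted p = 0.0173). Of 28 G2 and mitosis genes 2 fell (21 adjusted over the list alone), and of 30 S phase genes 0 (10 adjusted over the list alone). Astrocyte genes that rose were Sparcl1 at 1.13 ± 0.20, Aldh1l1 at 1.15 ± 0.22 and Gfap at 3.6 ± 0.76. Among the largest increases were Higd1b (5.31), Adamts2 (3.33) and Ccbe1 (3.31), and among the largest decreases Hbb-y (-6.56), Hba-x (-4.39), Robo3 (-4.20) and the transcription factor gene Ebf3 (-4.17). The total of 275 was 116 and 150 without E13.5 p18mKO2+ replicates 1 and 2, 76, 160 and 115 without E16.5 p18mKO2+ replicates 1, 2 and 3, 573 without E16.5 p18mKO2- replicate 3, 622 in a fit of these 6 libraries alone, 848 with DESeq2 and 970 without a filter, and, chosen after seeing the data, 116 without the libraries of both sexes and 150 with the Y-linked covariate.

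The p18 effect was then set against the averaged stage change, a contrast that shares the same libraries but is orthogonal to it in this balanced design. Of the 1224 genes higher in p18mKO2+ at E13.5, 1111 also rose with stage (195.6 for independent lists) and 4 fell. Of the 586 lower genes, 514 also fell with stage (81.8 for independent lists) and 1 rose. Across genes, which are not independent replicates, the E13.5 p18 effect and the stage change had a Pearson r of 0.537, a Spearman rho of 0.624 and a covariance of 0.447. In 100 simulations with no p18 effect r lay between -0.023 and 0.046 and the covariance reached 0.0262. These simulations drew each gene independently, whereas the estimated inter-gene correlation of the S phase list at E13.5 was 0.52. Their range therefore leaves out shifts that many genes of a library share, and is too narrow to measure chance. At E16.5 the r was -0.059, against -0.047 to 0.025 in those simulations, which for the same reason do not decide whether it lies beyond chance. Averaged over stages r was 0.395. It was 0.204 and 0.223 without E16.5 p18mKO2- replicates 1 and 3, 0.236 and 0.246 without E13.5 p18mKO2+ replicates 2 and 3, and 0.626 with the stricter filter. The contrasts are orthogonal only while the groups are of equal size. Without a library of either of these groups they share noise that by itself lowers r. The lower values therefore do not show how far r depends on those libraries. The 1006 genes that rose with stage over 2-fold had a median p18 effect of 1.32 at E13.5 and -0.07 at E16.5. For the 681 that fell over 2-fold these medians were -0.73 and 0.11. Averaged over stages the medians were 0.63 and -0.32 (camera with an estimated correlation, unadjusted p = 0.000596 and 0.025). For the 166 that fell by a log2 change over 2 the averaged median was -0.12.

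**Figure D4:**
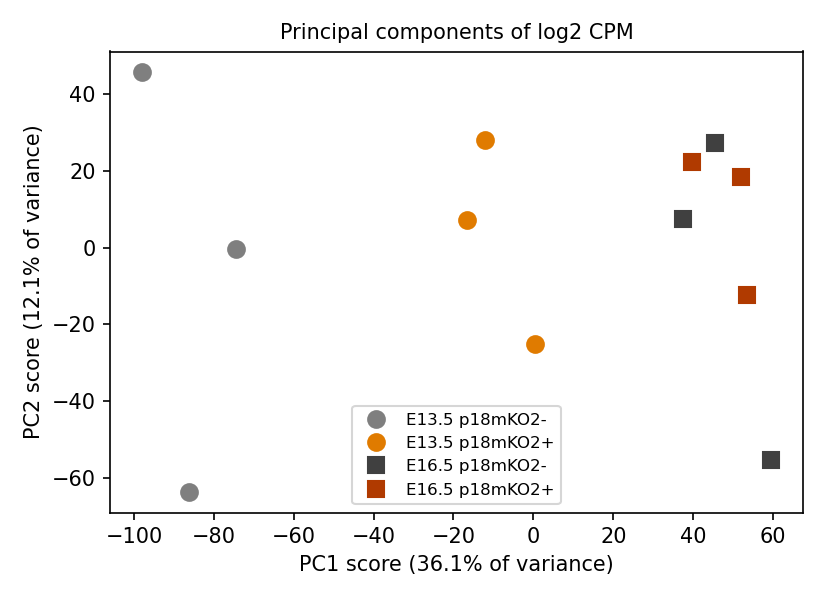
First and second principal components of log2 CPM over the 16798 tested genes, 1 point per library, with the share of variance on each axis. On the first component (36.1%) E13.5 p18mKO2+ libraries, from -16.7 to 0.4, lie between E13.5 p18mKO2- (-98 to -74.5) and the E16.5 libraries (37.4 to 59.5).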

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

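Of the tests weighed here, those of globins, progenitor lists, the striatal and interneuron lists, Cdkn2c length and the Y-linked and ribosomal RNA covariates were chosen only after the data were seen. The p18 effect differed between stages for 453 genes by the interaction test. Among the genes the rule names, P3h2 (3.77), Fndc3c1 (2.86), Hif3a (2.16), Slc43a1 (1.96), Xrcc3 (1.84) and AW047730 (1.77) had a more positive effect at E16.5 on the log2 scale. Inhba (-6.34), Mc4r (-4.96), Rgs6 (-4.54) and Dync1i1 (-4.24) had a more negative one, as did Scrg1 (-7.03), at 0 counts in E13.5 p18mKO2-, so that its fitted value is no bound, and Hist2h2aa1 (-6.43), which has a near-identical copy and is uncertain. The median difference was 0.86 for the S phase list, 0.84 for G2 and mitosis, -1.25 for pan-neuronal, -1.06 for deep-layer and -1.13 for upper-layer genes. Of 100 splits that exchanged the p18 label within stages, 7, the real one included, gave as many calls as the real 453 (highest other 963), so this share does not exclude chance. In a check made after this was seen, the 6 others kept the real E13.5 groups and so still held the E13.5 effect, while the 88 that broke those groups gave at most 1 call. The 12 splits that kept the E13.5 groups gave 230 to 963 calls, and 7 of them, the real one included, reached 453, so the real E16.5 groups did not stand out among them.

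The E13.5 p18mKO2+ libraries lay toward E16.5. Embryos further in development are a candidate explanation that the data leave open: the log2 ratio of embryonic to adult globin reads, which come from blood, was lower in p18mKO2+ by -2.63 ± 0.97 (SE, n = 3 each), although replicate 3, with the smallest shift (0.10 against 0.32 to 1.44 in p18mKO2-), had the highest pan-neuronal level of the 3. More postmitotic tissue stays open too: the S phase list changed by -0.65 ± 0.17 relative to radial glia and intermediate progenitor genes, but of these 36 genes 13 went up and 23 down (median -0.26, SD 0.70), a spread wider than their distance of 0.60 from the S phase median. The criterion written for this test, an S phase fall larger beyond its error, was met. However, the progenitor lists held genes that rose, by up to 2.03 in the radial glia list, which makes their mean fall smaller. The criterion therefore cannot decide whether such tissue was the whole cause. The spread of the members was a further condition outside that criterion, and is not the error of the distance. Of the 1810 calls, 38.7% stayed with the ribosomal RNA covariate and 51.3% with the Y-linked covariate, and the median change of the 1810 went from 0.91 (median SE 0.20) to 0.82 (0.22) and 0.96 (0.24), which argues against either as the whole cause. The real split gave 1810 calls and the highest of the 9 others 0, but 10 splits are too few for a share under 0.05; an effect of p18 itself, which the design names, stays open and is not separated from embryonic age.

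At E16.5 the ventral telencephalon list stood higher in p18mKO2+, a call lost with an estimated correlation (adjusted p = 0.108) and with fry (0.463), and the ribosomal RNA share differed between the same groups (9.42% against 2.84%), whose part in this change was not tested. The idea of ventral tissue came from values of other ventral genes; on lists holding no gene looked at before, 12 striatal genes changed by 0.92 ± 0.22 (log2, SE), none of them called (edgeR adjusted p = 1 for each), and without members under 1 CPM and Rxrg, which stood at 2.78 against 28.0 CPM, by 0.47 ± 0.11. The 10 cortical interneuron genes changed by 0.14 ± 0.03, which is 0.78 ± 0.21 less (0.33 ± 0.11 less without those members). Without those members the striatal change rested mostly on Adora2a (1.15 ± 0.30) and Sp9 (1.09 ± 0.38). The other striatal genes kept lay between 0.07 and 0.49, and the interneuron genes reached 0.57. A difference that rests on so few genes does not decide whether migrating interneurons were the whole cause at E16.5. At E13.5 both lists stood higher in p18mKO2+ than in p18mKO2-. There the striatal level was 1.93 to 2.75 against 1.39 to 1.85 (mean log2 CPM), and the cortical interneuron level 3.49 to 3.88 against 2.83 to 3.23. A difference between the lists was not tested at E13.5. Striatal or ganglionic eminence tissue in the dissected samples may account for the E16.5 pattern, but the abundant Pde1b (0.07), Pde10a (0.08) and Adcy5 (0.12) showed no called change at E16.5, and an effect of p18 on ventral genes was not tested. With 0 called genes in the real split (highest other 1), all 10 splits gave as many by construction, so they say nothing about this pattern.

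The deposited length of Cdkn2c, a value outside the count tests, was -258 bases in p18mKO2+ relative to p18mKO2- (exact permutation p = 0.03 over both stages, 0.3 at E13.5 and 0.2 at E16.5 alone). The test leaves open both reads of the transgene's coding sequence counted on Cdkn2c and a change in the transcripts of the gene itself, and the files do not separate them.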

How the results depend on the processing

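Deviations of same-numbered libraries correlated between -0.069 and 0.205. Between the E16.5 groups they correlated at 0.102, 0.061 and 0.15, each above the highest value of differently numbered libraries there (0.044). Between the E13.5 groups they did so at 0.015, -0.006 and 0.027, inside the range of the others (-0.114 to 0.099). Replicate 3 also had the lowest score on the second principal component in each group, so some shared replicate structure is possible. The replicate block gave 1937, 0, 389, 499, 5150 and 356 calls for the 6 comparisons, and ended none of the 7 list calls run with it (5 at E13.5 and 2 at E16.5). The cause of the changes below was not tested unless stated.

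For the p18 effect at E13.5 (1810 calls) leaving out 1 library gave 927 to 2383; the additions chosen after seeing the data gave 796 without the libraries of both sexes, 957 with the Y-linked covariate and 729 with the ribosomal RNA covariate. The median change of the 1810 genes was 0.91 (median SE 0.20) before, 0.96 (0.24) with the Y-linked and 0.82 (0.22) with the ribosomal RNA covariate. At E16.5 (0 calls) they gave 16 with DESeq2, 2 with limma-voom, 81 without a filter, 1 without the libraries of both sexes, and 0 to 1 leaving out 1 library. The average (374) gave 1127 with DESeq2, 1271 without a filter, 90, 17 and 0 with the same 3 additions, and 70 to 750 leaving out 1 library. With the ribosomal RNA covariate the median change of those 374 genes went from 0.72 (median SE 0.14) to 0.55 (0.24), so both a smaller change and a larger SE ended the calls, and 371 kept their sign. With the Y-linked covariate it went to 0.76 (0.20), so a larger SE and not a smaller change ended most calls. The difference between stages (453) gave 1122 with DESeq2, 1168 without a filter, 149 without the libraries of both sexes, 295 with the Y-linked covariate (median change 1.39 before and after, median SE 0.27 and 0.28), and 124 to 525 leaving out 1 library. The stage change in p18mKO2- (5005) stayed within 1.5 times, from 4103 to 5001 leaving out 1 library. In p18mKO2+ (275) it gave 848 with DESeq2, 970 without a filter, 622 with the 6 libraries alone, 116 and 150 with the first 2 additions, and 76 to 573 leaving out 1 library; with the Y-linked covariate the median change went from 1.12 (median SE 0.20) to 1.14 (0.22). For the average, 8 of 100 within-stage splits, the real one included, gave as many calls (highest other 1201), so this share does not exclude chance. The 7 others kept the real E13.5 groups and so held the E13.5 effect, while the 88 that broke them gave at most 1 call. The 12 that kept them gave 137 to 1201, and 8 of them, the real one included, reached 374, so the real E16.5 groups did not stand out. For the stage changes the real splits gave 5005 and 275 and the highest others 1 and 0, with 10 splits too few for a share under 0.05.

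Cdkn2c was not called in any setting run for it, which leaves out the 2 covariates. Leaving out 1 library its log2 change ranged from -0.067 to 0.269 at E13.5, 0.106 to 0.626 at E16.5, 0.123 to 0.384 for the average, 0.09 to 0.384 for the stage change in p18mKO2+, -0.035 to 0.484 for the difference between stages and -0.309 to 0.228 for the stage change in p18mKO2-, which was 0.026 without a filter and 0.014 without the libraries of both sexes. With an estimated correlation the E13.5 list calls ended (adjusted p 0.123 S phase, 0.247 G2 and mitosis, 0.12 pan-neuronal, 0.12 deep-layer, 0.0913 upper-layer), as did astrocytes (0.292) and GABAergic genes (0.108) at E16.5, where fry gave 0.655 and 0.463. The correlation with the stage change was 0.626 with the stricter filter and 0.204 to 0.459 leaving out 1 library. Leaving out 1 library ends the balance of the design, which by itself moves this correlation. No called named gene reversed in the settings run for single genes, which leave out the 2 covariates.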

Other observations

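Libraries differed in ways the labels do not give. Transcripts of Xist and of 4 Y-linked genes were both present in p18mKO2+ replicate 3 at E13.5 (1246 and 88.9 CPM) and at E16.5 (656 and 81.7 CPM). The 3 E13.5 p18mKO2- libraries held Xist at 1903 to 1937 CPM and Y-linked transcripts at 0.11 to 0.42 CPM. Y-linked transcripts stood at 178 CPM in E13.5 p18mKO2+ replicate 2 and at 135 and 182 CPM in E16.5 p18mKO2+ replicates 1 and 2. They stood at 168 CPM in E16.5 p18mKO2- replicate 2 and at 0 to 0.23 CPM in the remaining libraries. Y-linked expression was thus more frequent in p18mKO2+ than in p18mKO2- libraries, so sex and p18 status were partly confounded. The ribosomal RNA gene CT010467.1 took 7.38% ± 1.82 of counts in E13.5 p18mKO2- and 4.62% ± 1.92 in p18mKO2+, and 9.42% ± 3.76 and 2.84% ± 1.10 at E16.5 (SD, n = 3).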
